A study of Homo sapiens with 20 samples.

How the data were processed

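RNA-seq libraries were made from a pair of human cell lines, Panc1, a pancreatic ductal carcinoma line, and A549, a lung adenocarcinoma line. Each line was measured in 4 conditions: a control siRNA (siCont), the control siRNA with TGFβ, an siRNA against KLF10 (siKLF10), and siKLF10 with TGFβ. Per the labels' protocols, TGFβ was given at 5 ng/ml for 72 h, RNA was extracted as total RNA with TRIzol, and poly(A) RNA was made into libraries with a directional kit. Each condition had 3 libraries in Panc1 and 2 in A549, 20 in all, lettered A, B and C by the submitters. Nothing in the labels says whether same-condition libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

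The authors deposited 1 table of whole-number read counts per gene for each library. Per the submitters' processing notes, the tools used were TopHat, Bowtie2, HTSeq 0.6.0 and DESeq2 with the genome build hg19, with no role or order given. The strand setting of the counting is not given in the sources used here, so genes that overlap one another or have an antisense partner are uncertain. Reads with several alignments stand in a summary line of each table, so genes with near-identical copies rest on their unique reads and are uncertain too. Each table held 23368 genes and 5 summary lines. The summary lines name no gene and were left out of library sizes and tests. Reads in no annotated gene made up 33.6 to 37.0% of uniquely mapped reads in Panc1 and 57.6 to 60.2% in A549, and ambiguous reads 0.336 to 0.532%. No count was recorded in any library for 3385 genes. No genome or annotation of build hg19 was used here, so no coordinates are given.

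The authors also deposited tables of their own comparisons. Per the file headers, these tables hold base means (a signal of normalized counts), log2 fold changes with standard errors, a Wald test score, and p-values with adjusted p-values. Per the file headers, the deposited A549 siKLF10 table has an older layout, from which the fold change was read as a linear ratio. These values were used only to compare the tables with the count files and are named as the authors' wherever printed.

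Gene counts summed to 11152625 to 15571367 per library in Panc1 and 6846761 to 19070551 in A549. A floor of 3 counts corresponded to 0.157 to 0.438 CPM per library. Intervals and floors cover counting error only. A chi-square comparison of replicate pairs over genes with a mean count of at least 20 gave a chi-square per degree of freedom of 2.06 to 12.5 over 12 pairs in Panc1 and 2.22 to 11.4 over 4 pairs in A549, so no pair looked like 1 library deposited as a pair.

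Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), library sizes were scaled by TMM, and a group-means model was fitted per line with robust quasi-likelihood dispersions. All 4 groups of a line shared 1 estimate of the spread, with 8 residual degrees of freedom in Panc1 and 4 in A549. Differences between lines came from 1 model over all 20 libraries, with 12 residual degrees of freedom. The common biological coefficient of variation was 0.067 in both lines. The tests covered 13218 genes in Panc1, 14124 in A549 and 15058 in the joint model. Every adjusted p of a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. Levels are given as CPM, mean ± SD over the libraries of a group (n = 3 in Panc1, n = 2 in A549). These CPM are scaled by TMM, except in the accounts of interactions, of differences between lines, of genes near 0 and of the second expression profile, where they are plain CPM of gene counts. Log2 fold changes are given ± SE.

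The comparisons in each line were TGFβ against siCont, siKLF10 against siCont, siKLF10 with TGFβ against TGFβ, siKLF10 with TGFβ against siKLF10, and the interaction, which is the TGFβ response after siKLF10 minus that after siCont. A further 3 comparisons tested the difference of an effect between lines. These comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. KLF10, the targeted gene, is reported in every library. KLF10, SNAI1, SNAI2, ZEB1, CDH1, CDH2, VIM, FN1 and SMAD7 were named in every comparison whether called or not; 1 more gene fixed for this beforehand, and 1 gene eligible from a list, are not reported here. For the first 3 comparisons in each line, the 10 genes with the largest rise and the 10 with the largest fall were eligible. They had to be called, to average at least 5 CPM over the line, and to have groups that did not overlap, which chance alone gives for 10% of genes with 3 libraries against 3 and 33.3% with 2 against 2. For the other comparisons 5 and 5 were eligible, without the overlap condition for interactions and line differences. Up to 4 called members of each gene list were also eligible. Fewer are printed, taken from the top of each ranking. Y-linked genes and XIST are not named.

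There were 21 gene lists: TGFβ target genes, mesenchymal genes, epithelial genes, extracellular matrix genes, actin and contractile genes, cell cycle genes, the KLF and SP family, interferon-stimulated genes, unfolded protein response genes, cholesterol synthesis genes, p53 target genes, inflammatory genes, hypoxia and glycolysis genes, oxidative stress genes, immediate early genes, ribosomal protein genes, and markers of haematopoietic cells, endothelial cells, fibroblasts, lung cells and pancreatic cells. Lists with at least 3 measured members were tested against all other genes with camera (limma 3.58.1, log CPM with prior count 3, preset inter-gene correlation 0.01, Benjamini-Hochberg adjustment over the lists of a comparison). Camera was then repeated with an estimated correlation, and fry was run, which does not compare a list with other genes. A member that rose or fell passed the gene test over all genes.

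Correlations of fold changes between comparisons are across genes, which are not independent replicates. For the comparisons that share the siCont libraries, 20 draws per line of unchanged groups were simulated to give the correlation that shared controls produce with no effect, beside the overlap of independent lists.

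The fits were tested on simulated counts drawn from the measured means and library sizes, with 200 genes changed. For TGFβ against siCont in Panc1, run on 13065 genes, 82.1% of genes changed 1.5-fold were recovered, 97.0% of those changed 2-fold and 100% of those changed 4-fold, with 8 other genes called. For the same comparison in A549, run on 13867 genes, the shares were 68.7%, 82.1% and 97.0%, with 17 other genes called. For the Panc1 interaction, run on 13072 genes, they were 58.2%, 77.6% and 98.5%, with 10 others called. For the A549 interaction, run on 13890 genes, they were 46.3%, 74.6% and 98.5%, with 11 others called. For the line difference in the TGFβ response, run on 14418 genes, they were 55.2%, 73.1% and 95.5%, with 7 others called. Among 20 simulated lists, a list of 25 genes changed 1.3-fold was called by camera for TGFβ against siCont in Panc1 (adjusted p = 9.8e-41, 13090 genes) and in A549 (adjusted p = 8.63e-19, 13869 genes), with 0 other lists called. Genes were drawn independently of one another here. The simulated lists therefore held no inter-gene correlation, and these calls cannot show whether the preset correlation was high enough.

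Alternatives changed 1 choice at a time: DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a fit of only the groups compared, the replicate letter as a block, and each library left out in turn. Others were added after the data were seen: Panc1 comparisons without genes that a second expression profile could supply, gene lists without the first Panc1 siCont library, and siKLF10 comparisons without genes whose 3′ UTR holds one of 3 sequences of 7 bases. For the last of these, 3′ UTRs came from human transcripts of GENCODE v29, used for sequence only. For each sequence of 7 bases, the log2 fold change of genes of at least 5 CPM was regressed on its presence in the 3′ UTR of at least 20 bases, with the length and GC content of the 3′ UTR as covariates, log2 changes beyond 2 set to 2, and sequences present in at least 50 genes. The scan covered 10270 genes in Panc1 and 10782 in A549, was compared with 20 shuffles per line, and ranked first 10 of 10 sequences planted in each line. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps and the figures.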

Results

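RNA-seq read counts of 23368 genes were measured in Panc1 and A549 cells treated with a control siRNA (siCont) or an siRNA against KLF10 (siKLF10), each with or without TGFβ. KLF10 encodes a zinc-finger transcription factor induced early by TGFβ. The series asked whether KLF10 restrains the epithelial-to-mesenchymal transition that TGFβ triggers. Panc1 had 3 libraries in each of 4 groups and A549 had 2. Gene counts per library ranged from 11152625 to 15571367 in Panc1 and from 6846761 to 19070551 in A549.

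The targeted gene was examined first in every library. In Panc1, KLF10 measured 140, 137 and 130 CPM in siCont A, B and C, and 192, 187 and 206 CPM in TGFβ A, B and C. It measured 83.0, 80.8 and 77.5 CPM in siKLF10 A, B and C, and 101, 101 and 104 CPM in siKLF10 with TGFβ. In A549, KLF10 measured 110 and 107 CPM in siCont A and B, 179 and 179 CPM in TGFβ, 102 and 109 CPM in siKLF10, and 151 and 142 CPM in siKLF10 with TGFβ. The siRNA lowered KLF10 1.69-fold in Panc1 without TGFβ (log2 −0.76 ± 0.0603, adjusted p = 2.58e-09) and 1.92-fold with TGFβ (−0.94 ± 0.0593, adjusted p = 4.96e-11). In A549 without TGFβ, KLF10 did not differ between siKLF10 and siCont beyond the spread between libraries (−0.05 ± 0.0802, adjusted p = 0.743). With TGFβ it was lower in A549 siKLF10 (−0.29 ± 0.0779, adjusted p = 0.00775), a call that was lost without TGFβ A (adjusted p = 0.0624) or TGFβ B (adjusted p = 0.057). The A549 groups are therefore named as the libraries labelled siKLF10. The decrease of KLF10 was larger in Panc1 than in A549 without TGFβ (difference −0.68 ± 0.0996, adjusted p = 8.08e-06) and with it (−0.69 ± 0.0971, adjusted p = 3.33e-06).

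**Figure D1:**
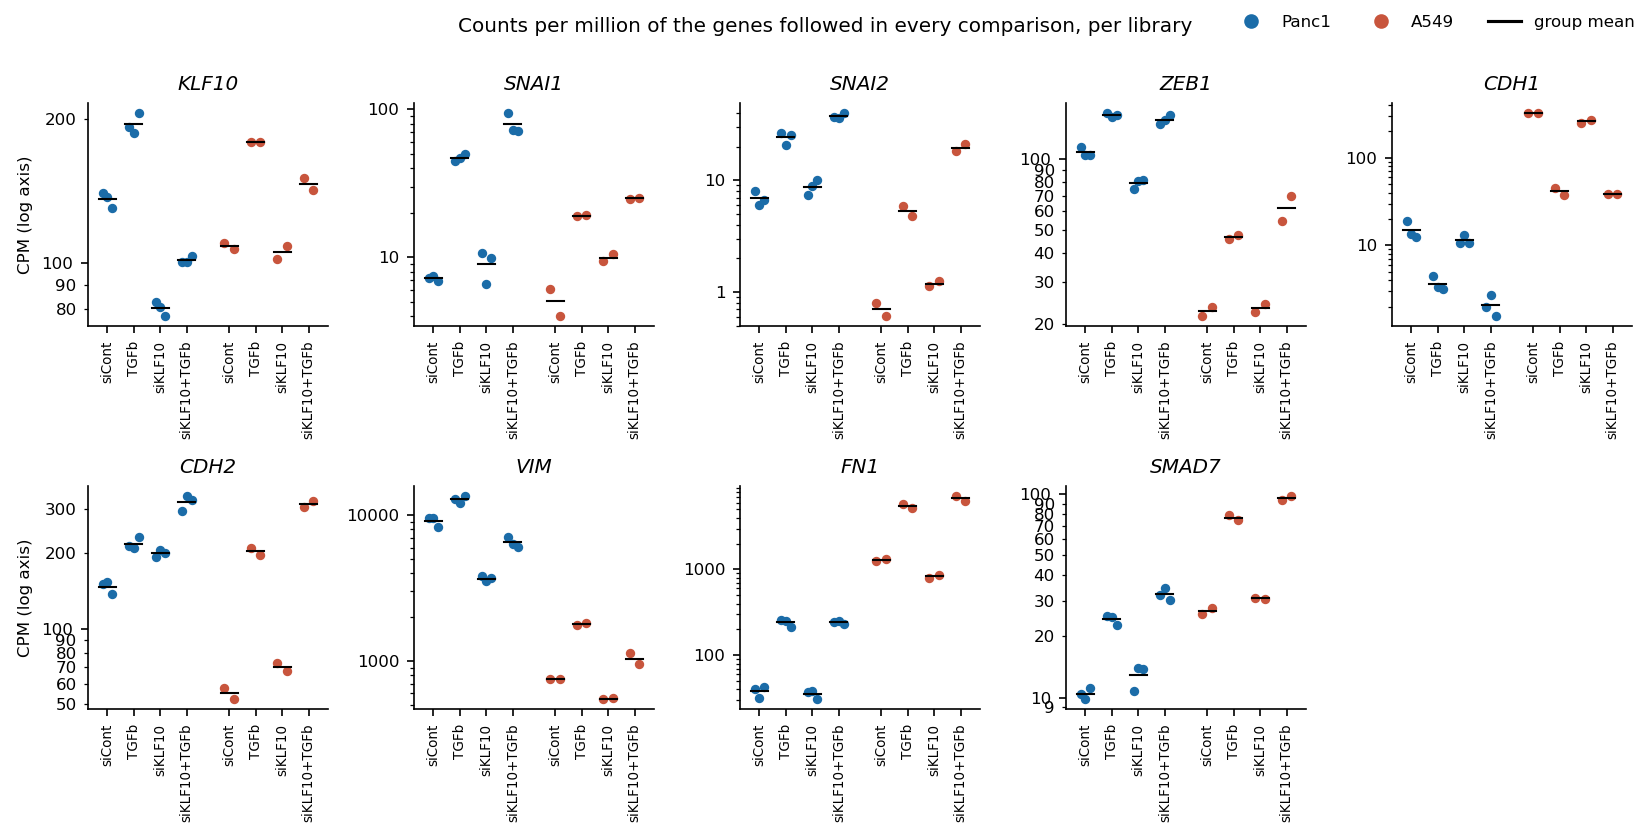
Normalised count (CPM, log axis) of the 9 genes named in every comparison, one panel per gene, in the 4 conditions of Panc1 (n = 3) and A549 (n = 2); points are libraries and short lines are group means. KLF10 averaged 80.4 CPM in Panc1 siKLF10 against 136 CPM in siCont, while the A549 libraries labelled siKLF10 averaged 105 CPM against 109 CPM.

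TGFβ moved Panc1 cells towards lower epithelial and higher mesenchymal and matrix transcripts. CDH1, which encodes E-cadherin of epithelial junctions, fell 4.09-fold, from 15.0 ± 3.3 to 3.64 ± 0.697 CPM (log2 −2.03 ± 0.179, adjusted p = 6.45e-09). SNAI1 and SNAI2, zinc-finger repressors of CDH1, rose by 2.70 ± 0.141 and 1.81 ± 0.128, and ZEB1, another such repressor, by 0.53 ± 0.0605. N-cadherin (CDH2) rose by 0.57 ± 0.0656, the intermediate filament gene VIM by 0.49 ± 0.0709, and SMAD7, an inhibitor of TGFβ signalling, by 1.22 ± 0.106. FN1, which encodes fibronectin, rose 6.28-fold. KLF10 itself rose by 0.52 ± 0.0583 (adjusted p = 2.39e-07). The largest rises were of PIK3AP1, an adaptor of PI3 kinase (15.0-fold, from 1.55 ± 0.191 to 23.5 ± 1.7 CPM), KANK4 (13.3-fold), the anchoring fibril collagen COL7A1 (12.8-fold), the α-tubulin TUBA4A (12.6-fold), the type I collagen chain COL1A1 (12.3-fold) and the metalloproteinase ADAM19 (12-fold). The largest falls were of INHBB, a subunit of activins (6.85-fold, from 55.3 ± 5.04 to 8.02 ± 1.44 CPM), the phosphatase subunit PPP2R2B (6.27-fold), ID2, an inhibitor of basic helix-loop-helix factors (5.97-fold), and the interferon-induced IFITM1 (5.61-fold).

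By gene list, 21 of 29 TGFβ targets rose and 4 fell in Panc1 with TGFβ (21 and 6 adjusted over the list alone). Camera gave an adjusted p = 1.15e-10, and examples beside ID2 were JUNB (2.49 ± 0.123) and PMEPA1 (2.48 ± 0.0592). Of 38 matrix genes 24 rose and 5 fell (26 and 5 adjusted over the list alone, camera adjusted p = 1.68e-10). Of 24 mesenchymal genes 16 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 5.08e-10). Of 20 actin and contractile genes 15 rose, with tropomyosin TPM1 at 2.24 ± 0.0585, and 1 fell (the same adjusted over the list alone, camera adjusted p = 6.54e-08). Of 31 epithelial genes 26 fell and 1 rose (27 and 1 adjusted over the list alone, camera adjusted p = 5.08e-10). Examples were the claudin CLDN3 (−2.33 ± 0.527), MAL2 (−2.25 ± 0.408) and keratin KRT19 (−1.93 ± 0.0753). The Panc1 siCont libraries also held transcripts that were low in the other 9 libraries: the basal keratin KRT5 stood at 59.9, 21.8 and 22.4 CPM in siCont A, B and C and at 5.20 to 9.35 CPM elsewhere. Such a profile could account for at least 10% of the siCont level of 155 tested genes (1.17%), which include the epithelial genes MAL2, EPCAM and KRT7 but not CDH1 or KRT19. Without those genes 21 of 23 epithelial genes fell (camera adjusted p = 5.84e-10), and without siCont A 23 of 31 fell (camera adjusted p = 3.6e-09). Interferon-stimulated genes fell, 13 of 26, and 2 rose (the same adjusted over the list alone, camera adjusted p = 4.27e-05). Beside IFITM1, examples were IFI44 at 1.49 ± 0.275, the antiviral GTPase MX1 at −1.32 ± 0.259 and IFIT2 at −1.20 ± 0.154. Of 14 inflammatory genes 8 fell and 3 rose (9 and 3 adjusted over the list alone, camera adjusted p = 0.0318). Examples were the cytokine IL11 at 2.87 ± 0.165, the prostaglandin synthase PTGS2 at 1.27 ± 0.245 and BIRC3 at −1.06 ± 0.0805. Of 23 cholesterol synthesis genes 8 fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 0.0318). Both of these calls were lost with an estimated correlation (adjusted p = 0.0891 for each with an estimated correlation), and the cholesterol call was also lost without siCont A (camera adjusted p = 0.0656).

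The remaining lists were not called in this comparison by camera, apart from the markers of fibroblasts and of pancreatic cells. In the KLF and SP family 6 of 17 genes rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.739). Examples were KLF17 at 1.77 ± 0.495, KLF4 at −1.60 ± 0.194 and KLF7 at 1.35 ± 0.108. The cell cycle list had 3 rises and 1 fall of 30 (the same adjusted over the list alone, camera adjusted p = 0.286). The unfolded protein list had 7 and 4 of 24 (the same adjusted over the list alone, camera adjusted p = 0.286). The p53 target list had 4 and 3 of 21 (4 and 4 adjusted over the list alone, camera adjusted p = 0.844). The hypoxia and glycolysis list had 6 rises and 8 falls of 23 (7 and 11 adjusted over the list alone, camera adjusted p = 0.626). The oxidative stress list had 3 and 7 of 19 (4 and 7 adjusted over the list alone, camera adjusted p = 0.379). The immediate early list had 4 and 8 of 16 (5 and 8 adjusted over the list alone, camera adjusted p = 0.676). Of 22 ribosomal protein genes 1 fell (0 adjusted over the list alone, camera adjusted p = 0.844). Fibroblast markers rose, 4 of 5 (the same adjusted over the list alone, camera adjusted p = 2e-04). FAP had 0.0485 CPM in siCont and 1.49 CPM with TGFβ, and the collagen COL3A1 rose by 1.16 ± 0.0975. Of 4 haematopoietic markers 1 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.626), of 5 lung cell markers 2 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.626), and the 1 measured endothelial marker rose. Of 3 pancreatic cell markers 1 fell (the same adjusted over the list alone, camera adjusted p = 0.0324, adjusted p = 0.0891 with an estimated correlation and camera adjusted p = 0.0506 without siCont A). In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3839 of 13218 genes, 1844 higher and 1995 lower with TGFβ, and 772 of them changed at least 2-fold.

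In Panc1 without TGFβ, cholesterol synthesis genes were lower and interferon-stimulated genes higher with siKLF10 than with siCont. Of 23 cholesterol genes 21 fell and 0 rose (the same adjusted over the list alone, camera adjusted p = 7.16e-13). Examples were the steroid dehydrogenase HSD17B7 (−1.13 ± 0.148), the isoprenoid synthase FDPS (−1.03 ± 0.0659) and the sterol sensor INSIG1 (−0.98 ± 0.0652). Of 26 interferon-stimulated genes 16 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 1.2e-07). Examples were IFI6 (1.93 ± 0.253), OAS2 (1.57 ± 0.235), MX1 (1.56 ± 0.186) and IFIT1 (1.44 ± 0.0903). VIM fell by 1.32 ± 0.0719, from 9158 ± 735 to 3673 ± 143 CPM (adjusted p = 7.51e-12), and ZEB1 fell by 0.44 ± 0.0622. CDH2 rose by 0.44 ± 0.0658 and SMAD7 by 0.30 ± 0.115 (adjusted p = 0.0434). CDH1 (−0.37 ± 0.152, adjusted p = 0.0618), SNAI1 (0.32 ± 0.172, adjusted p = 0.165), SNAI2 (0.34 ± 0.147, adjusted p = 0.072) and FN1 (−0.12 ± 0.112, adjusted p = 0.441) did not pass the test. The largest rises were of ARRDC4, an arrestin-family gene (5.02-fold, from 12.2 ± 0.363 to 61.5 ± 6.22 CPM), complement component C5 (4.30-fold), IFI6 (3.80-fold), CBLN2 (3.59-fold) and BMF, a pro-apoptotic BCL2 family member (3.58-fold). The largest falls were of KRT5 (5.75-fold, from 34.9 ± 22.3 to 6.06 ± 0.242 CPM), the mitochondrial assembly factor NDUFAF3 (5.25-fold), the integrin subunit ITGB5 (4.43-fold, from 214 ± 13.4 to 48.3 ± 1.08 CPM) and the secreted CTHRC1 (3.94-fold). KRT5 ranked first through siCont A, with a log2 fold change of −2.52 that was −1.87 without that library (adjusted p = 3.9e-08), and it belongs to the genes that the siCont profile could supply. NDUFAF3 and ITGB5 have a 3′ UTR site among the 3 sequences of 7 bases that were picked from the Panc1 siKLF10 effects.

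Epithelial genes were also lower after knockdown, 19 of 31 with 2 rises (22 and 2 adjusted over the list alone, camera adjusted p = 0.000541), but the call was lost with an estimated correlation (adjusted p = 0.179 with an estimated correlation). The leading members MAL2 (−2.45 ± 0.427) and KRT7 (−1.53 ± 0.402) belong to the genes that the siCont profile could supply. Without those genes 12 of 23 fell and 2 rose (camera adjusted p = 0.0135), and without siCont A 13 of 31 fell and 1 rose (camera adjusted p = 0.00329). Cell cycle genes fell, 18 of 30 with 4 rises (19 and 4 adjusted over the list alone, camera adjusted p = 0.00363, adjusted p = 0.0613 with an estimated correlation), although the cyclin CCNE2 rose by 0.85 ± 0.0959 and the nucleotide reductase subunit RRM2 by 0.66 ± 0.0574. Hypoxia and glycolysis genes fell, 13 of 23 with 4 rises (the same adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.275 with an estimated correlation). Examples were ANKRD37 at −1.36 ± 0.279 and the glycolytic regulator PFKFB3 at −1.31 ± 0.112. TGFβ targets had 5 rises and 11 falls of 29 (the same adjusted over the list alone, camera adjusted p = 0.236). The KLF and SP family had 1 rise and 7 falls of 17 (2 and 8 adjusted over the list alone, camera adjusted p = 0.0866). The edgeR test called 4700 genes, 2286 higher and 2414 lower, of which 418 changed at least 2-fold. The SMAD7 call was lost with DESeq2 (adjusted p = 0.0797) and without siCont A, siCont B, siKLF10 B or siKLF10 C (adjusted p = 0.0919, 0.137, 0.163 and 0.163).

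Under TGFβ, SNAI1 and SNAI2 were higher and CDH1 lower in Panc1 with siKLF10 than with siCont. SNAI1 rose from 47.0 ± 2.54 to 79.4 ± 13 CPM (log2 0.76 ± 0.111, adjusted p = 2.19e-05) and SNAI2 from 24.2 ± 3.18 to 37.5 ± 2.14 CPM (0.63 ± 0.106, adjusted p = 6.16e-05). CDH1 fell from 3.64 ± 0.697 to 2.08 ± 0.572 CPM (−0.80 ± 0.25, adjusted p = 0.0127). CDH2 rose by 0.55 ± 0.0647 and SMAD7 by 0.40 ± 0.0941. VIM, in contrast, fell by 0.98 ± 0.0714, from 12890 ± 703 to 6519 ± 543 CPM (adjusted p = 4.76e-10). FN1 stood at 242 ± 24.4 and 242 ± 12.4 CPM (adjusted p = 0.985) and ZEB1 at 155 ± 3.03 and 148 ± 6.58 CPM (adjusted p = 0.377). The largest rises were of the arginase ARG2 (8.10-fold), the focal adhesion protein gene TNS1 (4.23-fold, from 4.53 ± 0.866 to 19.1 ± 0.35 CPM), C20orf160 (4.16-fold) and ABAT, an enzyme of GABA breakdown (3.87-fold). The largest falls were of ITGB5 (6.04-fold, from 467 ± 13.7 to 77.3 ± 1.23 CPM, adjusted p = 2.21e-18), NDUFAF3 (5.66-fold), MREG (5.25-fold) and RAB27B, a small GTPase of vesicle secretion (4.39-fold). Each of these falls has a 3′ UTR site among the 3 sequences of 7 bases that were picked from the Panc1 siKLF10 effects.

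Cholesterol genes were the 1 list called here, with 16 of 23 lower and 0 higher (the same adjusted over the list alone, camera adjusted p = 1.43e-05). Examples were HSD17B7 (−1.17 ± 0.15), FDPS (−0.83 ± 0.0656) and MVD (−0.82 ± 0.0985). Of 29 TGFβ targets 17 rose and 6 fell (18 and 7 adjusted over the list alone, camera adjusted p = 0.0623). Examples were the TGFβ pseudoreceptor BAMBI (1.46 ± 0.468), the binding protein LTBP2 (−1.0 ± 0.0594) and IGFBP3 (0.99 ± 0.0732). Of 38 matrix genes 13 rose and 7 fell (13 and 8 adjusted over the list alone, camera adjusted p = 0.396). Examples were thrombospondin THBS1 at 1.54 ± 0.0847 and the proteoglycan VCAN at 1.35 ± 0.14. In this comparison edgeR called 5513 genes, 2794 higher and 2719 lower, 477 of them at least 2-fold. The CDH1 call was lost without TGFβ A (adjusted p = 0.0746) or siKLF10 with TGFβ C (adjusted p = 0.0579).

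After knockdown, the TGFβ response of Panc1 ran in the same direction for most genes. SNAI1 rose by 3.14 ± 0.135, SNAI2 by 2.09 ± 0.121, ZEB1 by 0.90 ± 0.0619, CDH2 by 0.68 ± 0.065, VIM by 0.83 ± 0.0712, FN1 by 2.77 ± 0.106, SMAD7 by 1.32 ± 0.102 and KLF10 by 0.34 ± 0.0609, and CDH1 fell by 2.47 ± 0.209 (adjusted p = 2.09e-09). TNS1 rose from 0.398 ± 0.215 to 19.1 ± 0.35 CPM and TUBA4A 40.8-fold, from 5.73 ± 0.333 to 234 ± 33.6 CPM, while PPP2R2B fell 13-fold and ITGB4, an integrin of hemidesmosomes, fell 7.33-fold. Of 29 TGFβ targets 22 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 4.75e-11). Of 26 interferon-stimulated genes 18 fell and 1 rose (19 and 1 adjusted over the list alone, camera adjusted p = 1.16e-09). Of 30 cell cycle genes 21 rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 8.7e-06). Examples were the kinetochore gene CENPF (0.51 ± 0.0743) and the replication licensing gene CDC6 (0.46 ± 0.0638). In total 5943 genes were called, 2993 higher and 2950 lower, 1079 of them at least 2-fold. Across 13218 genes the TGFβ effects with and without knockdown, which share no libraries, correlated with r = 0.81. Of the genes called in both, 1477 rose in both, 1535 fell in both and 37 went opposite ways, against 418, 445 and 863 for independent lists.

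Whether the TGFβ response differed between siKLF10 and siCont was tested as the interaction. In Panc1, TNS1 (2.30 ± 0.556, adjusted p = 0.0176), the AP-1 subunit FOSB (2.17 ± 0.244, adjusted p = 1.23e-05) and C20orf160 (2.14 ± 0.205) had the largest positive interactions. FOSB stood at 4.19 ± 0.459, 4.12 ± 0.718, 3.33 ± 0.311 and 13.9 ± 2.1 CPM in siCont, TGFβ, siKLF10 and both together. TRANK1 (−1.48 ± 0.224) and PADI2, a protein-citrullinating enzyme (−1.31 ± 0.0794, adjusted p = 1.01e-09), had the largest negative ones, and PADI2 stood at 121 ± 7.58, 321 ± 4.46, 204 ± 3.31 and 207 ± 3.86 CPM in the same order. Among the 9 genes named throughout, ZEB1 was called (0.37 ± 0.0863, adjusted p = 0.0146), and the others were not: KLF10 (−0.18 ± 0.0843), SNAI1 (0.44 ± 0.205), SNAI2 (0.28 ± 0.181), CDH1 (−0.43 ± 0.293), CDH2 (0.11 ± 0.0921), VIM (0.34 ± 0.1), FN1 (0.12 ± 0.146) and SMAD7 (0.10 ± 0.149). TGFβ targets had positive interactions, 10 of 29 positive and 0 negative (13 and 0 adjusted over the list alone, camera adjusted p = 1.55e-08). Examples were NEDD9 (1.37 ± 0.264), ID1 (0.95 ± 0.133) and RHOB (0.94 ± 0.1). NEDD9 belongs to the genes that the siCont profile could supply. Without those genes 9 of 28 TGFβ targets were positive and 0 negative (camera adjusted p = 3.64e-08). Cell cycle genes had 6 of 30 positive and 0 negative (13 and 0 adjusted over the list alone, camera adjusted p = 3.6e-07). Cholesterol genes had 8 of 23 positive and 0 negative (11 and 0 adjusted over the list alone, camera adjusted p = 3.13e-05). Interferon-stimulated genes had 7 of 26 negative and 0 positive (9 and 0 adjusted over the list alone, camera adjusted p = 1.09e-10). Examples were IFIT1 (−0.87 ± 0.142). Hypoxia and glycolysis genes had 6 of 23 positive and 1 negative (13 and 3 adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.0929 with an estimated correlation). Immediate early genes had 3 of 16 positive and 1 negative (6 and 1 adjusted over the list alone, camera adjusted p = 0.00459, adjusted p = 0.296 with an estimated correlation). The camera calls of the epithelial list (3 positive and 1 negative of 31, the same adjusted over the list alone, camera adjusted p = 0.0202) and of the matrix list (6 and 2 of 38, 8 and 4 adjusted over the list alone, camera adjusted p = 0.0492) were lost with an estimated correlation (adjusted p = 0.361 and adjusted p = 0.315 with an estimated correlation) and without siCont A (camera adjusted p = 0.0924 and 0.0505). Without siCont A the positive members were 2 of 30 cell cycle genes (camera adjusted p = 4.29e-07), 5 of 23 cholesterol genes (3.17e-05), 4 of 23 hypoxia and glycolysis genes (6.22e-05) and 1 of 16 immediate early genes (0.0063), while 10 of 29 TGFβ targets were positive and 7 of 26 interferon-stimulated genes negative. The interaction covered 584 genes, 338 positive and 246 negative, 68 of them at least 2-fold. This count was 349 without siKLF10 with TGFβ B and 1035 without siKLF10 with TGFβ A. The ZEB1 call was lost without siCont A (adjusted p = 0.051) or TGFβ B (adjusted p = 0.0544), and the TNS1 call without siCont B (adjusted p = 0.172).

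**Figure D2:**
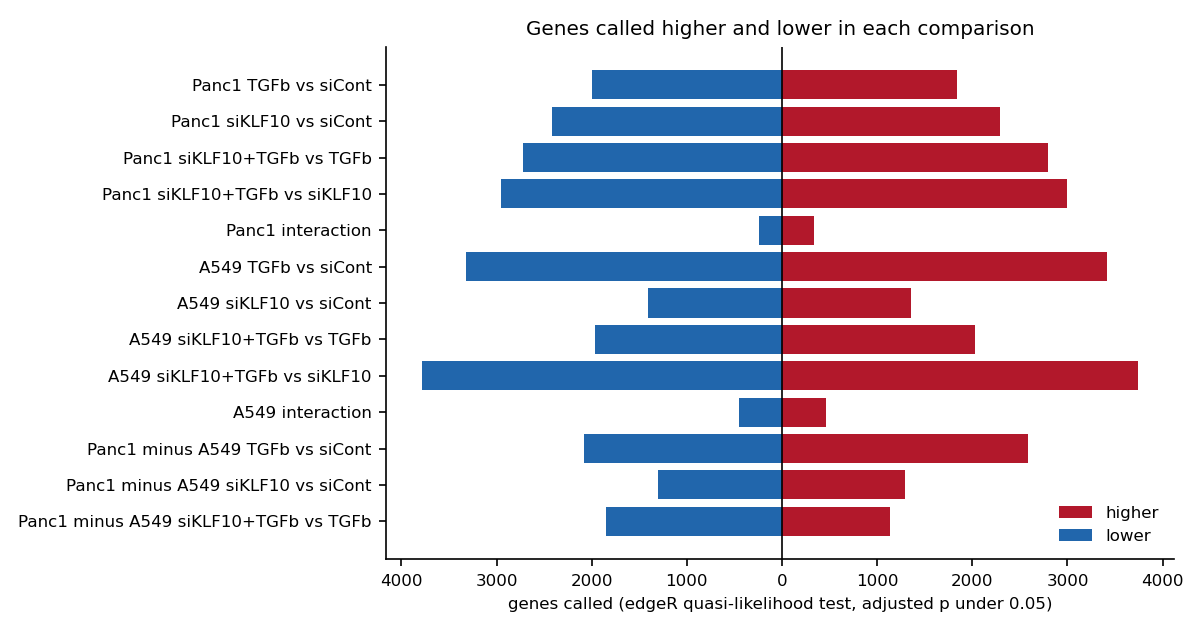
Number of genes called by edgeR's quasi-likelihood test (adjusted p under 0.05) in the 10 comparisons within Panc1 and A549 and the 3 differences between lines, with bars for genes higher (right of 0) and lower (left of 0). TGFβ against siCont had 1844 higher and 1995 lower genes in Panc1, and 3416 and 3317 in A549.

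A549 cells also responded to TGFβ. CDH1 fell 7.77-fold, from 322 ± 2.99 to 41.2 ± 4.74 CPM (log2 −2.96 ± 0.0913, adjusted p = 6.13e-17). SNAI1 rose by 1.89 ± 0.17, SNAI2 by 2.89 ± 0.307, ZEB1 by 1.05 ± 0.121, CDH2 by 1.89 ± 0.0856, VIM by 1.26 ± 0.0818, FN1 by 2.09 ± 0.0871, SMAD7 by 1.53 ± 0.0945 and KLF10 by 0.72 ± 0.0789. The largest rises were of genes with few or no counts in siCont. SLAMF9, a receptor of the SLAM family, went from 0 to 522 counts in the 2 libraries of each group, at least 249-fold higher against a floor of 3 counts over the group. The cornified envelope gene LCE3E went from 1 to 1131 counts, a ratio of 1620 (95% counting interval 290 to 64100), and the phospholipid flippase ATP8A2 from 0 to 247 counts, at least 118-fold higher. The largest falls were of the tetraspanin-like TM4SF20 (119-fold, from 94.1 ± 2.37 to 0.75 ± 0.22 CPM), TSPAN8 (76.5-fold), the keratin KRT4 (69.5-fold), FCGBP, a mucus protein (69.0-fold), and AGR2, a disulfide isomerase of mucin-secreting cells (63.9-fold, from 481 ± 15 to 7.34 ± 1.57 CPM). Of 37 matrix genes 31 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 4.6e-13). Examples were collagenase MMP1 at 7.65 ± 0.215 and the metalloproteinase inhibitor TIMP3 at 5.97 ± 0.298. Of 29 TGFβ targets 24 rose and 4 fell (25 and 4 adjusted over the list alone, camera adjusted p = 2.23e-09). An example was CTGF at 4.58 ± 0.111. Of 20 actin and contractile genes 17 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 8.64e-06). The largest was TAGLN at 3.12 ± 0.0884. Of 26 mesenchymal genes 21 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 2.19e-09, adjusted p = 0.0739 with an estimated correlation). The largest was gelatinase MMP2 at 6.35 ± 0.113. Measured members of the lung cell list fell, 8 of 10 with 0 rises (the same adjusted over the list alone, camera adjusted p = 2.16e-06). Examples were the fibrinogen chains FGA at −4.59 ± 0.113 and FGG at −4.17 ± 0.0941. SFTPB, SFTPC, SCGB1A1 and NKX2-1 of this list were too low to be tested in A549. AKR1B10, AKR1C1, ALDH1A1 and ALDH3A1 also stand in the oxidative stress list. The falls of this list therefore do not show a loss of lung identity.

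Further lists were called in A549 with TGFβ at the preset correlation and lost with an estimated one. Of 36 epithelial genes 23 fell and 4 rose (23 and 5 adjusted over the list alone, camera adjusted p = 9.64e-05, adjusted p = 0.17 with an estimated correlation). Examples were the receptor ERBB3 at −3.28 ± 0.144 and, in the other direction, the claudin CLDN4 at 3.69 ± 0.141. Of 21 oxidative stress genes 19 fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 1.28e-09, adjusted p = 0.148 with an estimated correlation). The largest was the aldo-keto reductase AKR1B10 at −3.32 ± 0.126. Of 22 inflammatory genes 13 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.00023, adjusted p = 0.0648 with an estimated correlation). CSF2 had 0 CPM in siCont and 3.51 CPM with TGFβ, and the cytokine IL1A rose by 6.59 ± 0.266. Of 22 p53 targets 13 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00223, adjusted p = 0.0739 with an estimated correlation). Examples were the stress cytokine GDF15 at −2.25 ± 0.143 and TP53I3 at 1.71 ± 0.0862. Of 18 immediate early genes 13 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.00262, adjusted p = 0.17 with an estimated correlation). Of 22 ribosomal protein genes 10 fell and 0 rose (the same adjusted over the list alone, camera adjusted p = 0.0437, adjusted p = 0.575 with an estimated correlation). Of 5 fibroblast markers 4 rose (the same adjusted over the list alone, camera adjusted p = 0.0205, adjusted p = 0.182 with an estimated correlation). Interferon-stimulated genes (5 rises and 9 falls of 25, the same adjusted over the list alone, camera adjusted p = 0.216) and cholesterol genes (3 and 9 of 24, the same adjusted over the list alone, camera adjusted p = 0.153) were not called. The edgeR test called 6733 of 14124 genes, 3416 higher and 3317 lower, 2252 of them at least 2-fold.

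In A549 without TGFβ, the libraries labelled siKLF10 differed from siCont although KLF10 did not pass the test. FN1 fell by 0.63 ± 0.0846, from 1292 ± 49.6 to 835 ± 47 CPM (adjusted p = 1.77e-05), VIM fell by 0.44 ± 0.0814 and CDH1 by 0.31 ± 0.0793. SNAI1 rose by 0.94 ± 0.186 and CDH2 by 0.35 ± 0.0882. SNAI2 (0.71 ± 0.426, adjusted p = 0.274), ZEB1 (adjusted p = 0.869) and SMAD7 (0.21 ± 0.101, adjusted p = 0.149) did not pass. The largest rises were of the hyaluronan-binding TNFAIP6 (from 0.248 ± 0.145 to 1.76 ± 0.276 CPM), IGSF10 (5.04-fold), the protease MMP10 (from 0.204 ± 0.0831 to 0.896 ± 0.0833 CPM) and GATSL3 (4.19-fold). The largest falls were of the vitamin C transporter SLC23A1 (6.17-fold, from 19.4 ± 0.822 to 3.26 ± 0.921 CPM), the bile acid conjugating enzyme BAAT (5.56-fold), DCDC5 (5.43-fold) and the claudin CLDN2 (4.88-fold). Of 22 p53 targets 9 rose and 0 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000134, adjusted p = 0.0943 with an estimated correlation). Examples were the cell cycle inhibitor CDKN1A (1.34 ± 0.0827), BTG2 (0.93 ± 0.126) and the death receptor TNFRSF10B (0.87 ± 0.0809). Measured members of the lung cell list fell, 8 of 10 with 0 rises (the same adjusted over the list alone, camera adjusted p = 2.54e-05, adjusted p = 0.0943 with an estimated correlation). The largest fall was that of fibrinogen FGB at −1.71 ± 0.0849. Matrix genes rose, 14 of 37 with 3 falls (17 and 3 adjusted over the list alone, camera adjusted p = 0.0032, adjusted p = 0.334 with an estimated correlation). Mesenchymal genes rose, 9 of 26 with 3 falls (9 and 4 adjusted over the list alone, camera adjusted p = 0.0191, adjusted p = 0.652 with an estimated correlation). Immediate early genes rose too, 5 of 18 with 0 falls (the same adjusted over the list alone, camera adjusted p = 0.00355, adjusted p = 0.334 with an estimated correlation). The edgeR test called 2758 genes, 1351 higher and 1407 lower, 403 of them at least 2-fold, and DESeq2 called 1676. Leaving out any 1 of the 4 libraries lowered the count, to 1326 without siCont B and up to 1638 without siKLF10 B. The CDH1 call was lost without siCont A, siCont B or siKLF10 A (adjusted p = 0.0683, 0.0895 and 0.118), the CDH2 call without siCont B or siKLF10 A (0.142 and 0.124), and the MMP10 call without siCont A or siKLF10 A (0.133 and 0.123).

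With TGFβ, cell cycle genes were lower in the A549 libraries labelled siKLF10. Of 30 cell cycle genes 24 fell and 0 rose (25 and 0 adjusted over the list alone, camera adjusted p = 1.91e-10, adjusted p = 0.162 with an estimated correlation). Examples were HMMR (−0.85 ± 0.102), the mitotic activator CDC20 (−0.84 ± 0.113) and Aurora kinase AURKB (−0.71 ± 0.0933). Of 22 inflammatory genes 16 fell and 3 rose (17 and 3 adjusted over the list alone, camera adjusted p = 7.64e-05, adjusted p = 0.109 with an estimated correlation). Examples were the cytokine CSF2 (−3.10 ± 0.477) and the chemokine CCL20 (−1.38 ± 0.255). Actin and contractile genes fell, 11 of 20 with 0 rises (the same adjusted over the list alone, camera adjusted p = 0.0066, adjusted p = 0.162 with an estimated correlation). Unfolded protein genes rose, 12 of 24 with 1 fall (13 and 1 adjusted over the list alone, camera adjusted p = 0.00235, adjusted p = 0.246 with an estimated correlation). Matrix genes had 15 rises and 4 falls of 37 (17 and 4 adjusted over the list alone, camera adjusted p = 0.00359, adjusted p = 0.246 with an estimated correlation). Mesenchymal genes had 15 and 4 of 26 (15 and 5 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.452 with an estimated correlation). Measured members of the lung cell list fell, 6 of 10 with 0 rises (the same adjusted over the list alone, camera adjusted p = 0.000113, adjusted p = 0.109 with an estimated correlation). Ribosomal protein genes fell, 5 of 22 with 0 rises (4 and 0 adjusted over the list alone, camera adjusted p = 0.0225, adjusted p = 0.579 with an estimated correlation). SNAI2 rose by 1.87 ± 0.172, from 5.29 ± 0.766 to 19.5 ± 1.86 CPM (adjusted p = 5.9e-08), CDH2 by 0.63 ± 0.0795, ZEB1 by 0.43 ± 0.111, SNAI1 by 0.39 ± 0.137, SMAD7 by 0.32 ± 0.0859 and FN1 by 0.29 ± 0.0836, while VIM fell by 0.79 ± 0.081. CDH1 stood at 41.2 ± 4.74 and 38.4 CPM (adjusted p = 0.426). The granin SCG2 rose from 4.37 ± 0.509 to 219 ± 53 CPM (49.6-fold), the potassium channel subunit KCNE4 14.1-fold, TMEM132E 11.3-fold and IGFBP5, a binding protein of insulin-like growth factors, 9.03-fold. GGT5 (8.41-fold), the mucin MUC5B (8.27-fold), PDZK1IP1 (8.10-fold) and TAGLN, an actin-binding protein (6.94-fold, from 416 ± 13.7 to 60.1 ± 4.08 CPM), fell most. The edgeR test called 3996 genes, 2029 higher and 1967 lower, 561 of them at least 2-fold, and 2237 without TGFβ A. Without TGFβ A the calls of SNAI1 (adjusted p = 0.204) and ZEB1 (adjusted p = 0.0873) were lost, and without TGFβ B those of SNAI1 (adjusted p = 0.134), FN1 (adjusted p = 0.187) and SMAD7 (adjusted p = 0.0935).

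The TGFβ response of the A549 libraries labelled siKLF10 included rises of SNAI2 (4.05 ± 0.227), FN1 (3.01 ± 0.0905), CDH2 (2.17 ± 0.0852), SMAD7 (1.64), ZEB1 (1.44 ± 0.119), SNAI1 (1.34 ± 0.149), VIM (0.91 ± 0.0818) and KLF10 (0.48 ± 0.0794), and a fall of CDH1 (−2.76 ± 0.089, adjusted p = 1.2e-16). ATP8A2 went from 0 to 627 counts (at least 130-fold higher), and KRT4 fell from 597 to 3 counts, a ratio of 320 (95% counting interval 109 to 1550). Of 30 cell cycle genes 25 fell and 2 rose (26 and 2 adjusted over the list alone, camera adjusted p = 1.17e-06, adjusted p = 0.194 with an estimated correlation). Of 37 matrix genes 29 rose and 3 fell (30 and 3 adjusted over the list alone, camera adjusted p = 8.14e-12, adjusted p = 0.0697 with an estimated correlation). In total 7522 genes were called, 3741 higher and 3781 lower, 2508 of them at least 2-fold. Across 14124 genes this response correlated with that after siCont at r = 0.893, with 2757 genes rising and 2558 falling in both and 47 going opposite ways.

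The A549 interaction was led by SCG2 (4.83 ± 0.603, adjusted p = 0.00059), at 1.25 ± 0.294, 4.27 ± 0.465, 2.14 ± 0.0315 and 212 ± 52.2 CPM in siCont, TGFβ, siKLF10 and both together, by IGFBP5 (3.71 ± 0.277, adjusted p = 7.84e-08) and by the complement regulator CFI (3.28 ± 0.327). Its largest negative values were those of MMP10 (−2.84 ± 0.578) and TNFAIP6 (−2.62 ± 0.482). Of the 9 genes named throughout, FN1 (0.92 ± 0.119, adjusted p = 5.83e-05) was called, and KLF10, SNAI1 (−0.56 ± 0.232), SNAI2 (1.16 ± 0.479), ZEB1, CDH1 (0.20 ± 0.124), CDH2, VIM (−0.35 ± 0.114) and SMAD7 were not (adjusted p = 0.0785 to 0.725). Cell cycle genes had 18 of 30 negative and 0 positive (24 and 0 adjusted over the list alone, camera adjusted p = 1.11e-11, adjusted p = 0.142 with an estimated correlation). Inflammatory genes had 11 of 22 negative and 1 positive (13 and 1 adjusted over the list alone, camera adjusted p = 8.07e-07, adjusted p = 0.108 with an estimated correlation). Actin and contractile genes had 7 of 20 negative and 0 positive (9 and 0 adjusted over the list alone, camera adjusted p = 0.000906, adjusted p = 0.142 with an estimated correlation). The interaction covered 916 genes, 460 positive and 456 negative, 172 of them at least 2-fold. DESeq2 called 554, and the count ran from 379 without siCont B to 2685 without siKLF10 with TGFβ A. The MMP10 call was lost without siKLF10 A (adjusted p = 0.078).

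**Figure D3:**
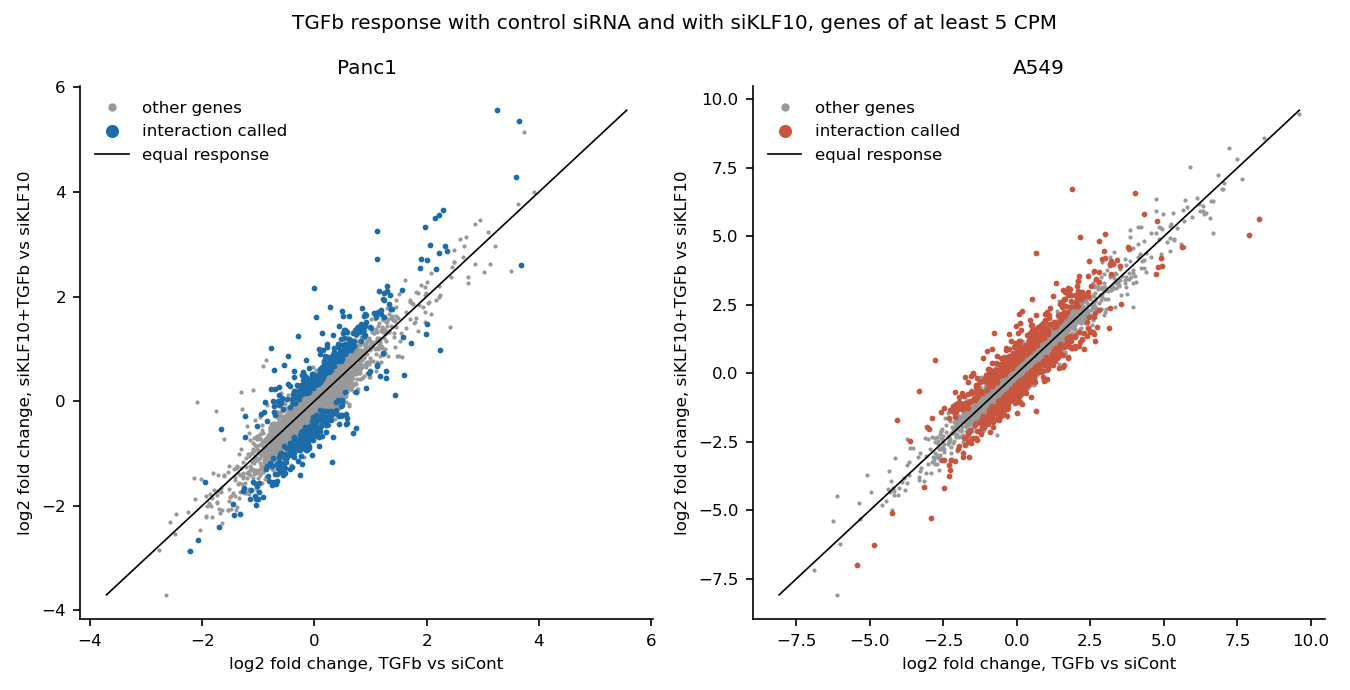
TGFβ response (log2 fold change) with siCont on the horizontal axis and with siKLF10 on the vertical axis in Panc1 and A549. Each point is a gene of at least 5 CPM, coloured where the interaction was called by edgeR, and the line marks equal responses. Genes at or below a floor of 3 counts over any group, such as SLAMF9, LCE3E and ATP8A2 in A549, are not drawn. This leaves 10604 genes in Panc1 and 11203 in A549. Across genes of at least 5 CPM, drawn or not, r was 0.871 in Panc1 and 0.933 in A549.

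**Figure D4:**
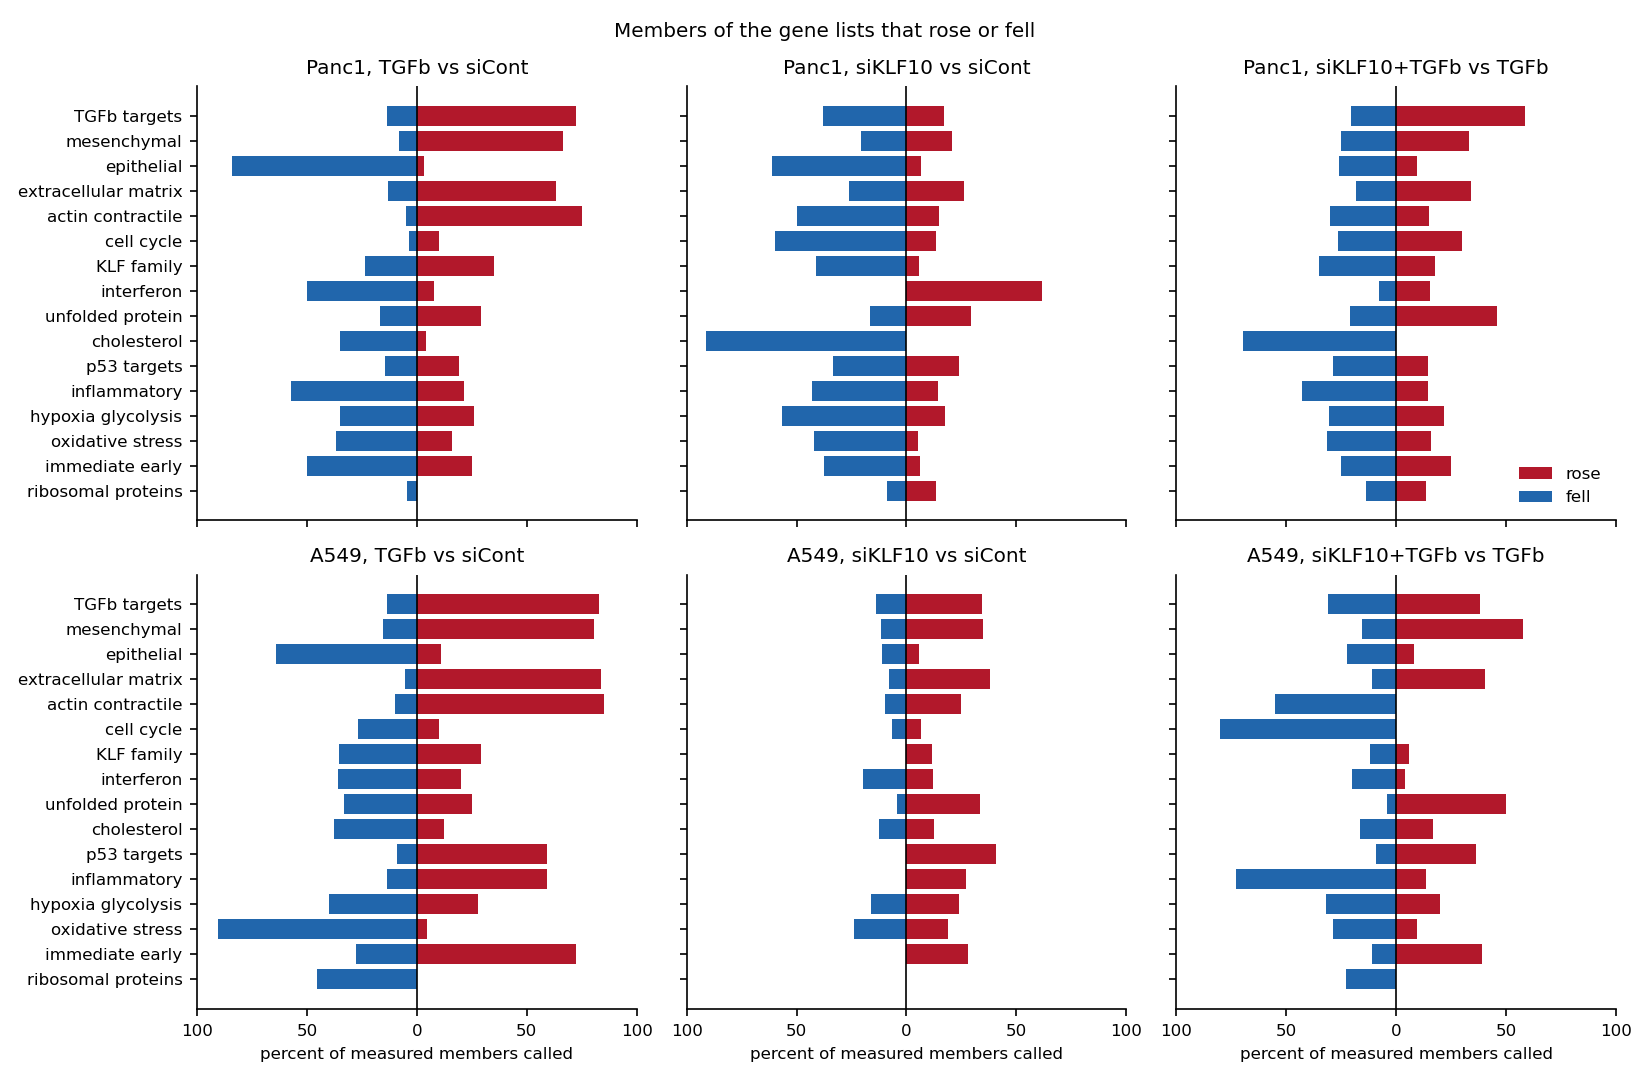
Percent of the measured members of 16 gene lists that rose (bars to the right of 0) or fell (to the left) in 3 comparisons of Panc1 and of A549. Cholesterol synthesis genes had 21 falls and 0 rises among 23 members in Panc1 siKLF10 against siCont, and cell cycle genes 24 falls and 0 rises among 30 in A549 siKLF10 with TGFβ against TGFβ.

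Differences between the lines were tested in a model of all 20 libraries. The TGFβ response of FGG, a fibrinogen chain, differed most in the positive direction (5.24 ± 0.418, adjusted p = 4.71e-12), as it fell from 490 ± 46.7 to 25.7 ± 0.269 CPM in A549 and stood at 0.38 ± 0.125 and 0.752 ± 0.245 CPM in Panc1. At the other end stood IGFL1, at 0.17 ± 0.168 and 0.0498 ± 0.0433 CPM in Panc1 and 0.111 ± 0.158 and 98.5 CPM in A549, and CORO2B, an actin-binding coronin (adjusted p = 1.01e-21), at 6.35 ± 0.518 and 5.62 ± 0.426 CPM in Panc1 and 0.211 ± 0.0879 and 69.0 ± 1.61 CPM in A549. The response was smaller in Panc1 for CDH2 (−1.24 ± 0.114), SNAI2 (−1.01 ± 0.385), VIM (−0.68 ± 0.111) and ZEB1 (−0.44 ± 0.133), and more positive for SNAI1 (0.89 ± 0.253), FN1 (0.64 ± 0.142) and CDH1 (1.005 ± 0.213), which fell less in Panc1. KLF10 (−0.12 ± 0.0972, adjusted p = 0.396) and SMAD7 (adjusted p = 0.238) did not differ beyond the spread between libraries. Inflammatory genes, of which more fell than rose in Panc1 and more rose than fell in A549, had negative differences (14 of 22 negative and 1 positive, 17 and 1 adjusted over the list alone, camera adjusted p = 7.14e-09). Matrix genes had negative differences too (24 of 39 negative and 7 positive, 25 and 8 adjusted over the list alone, camera adjusted p = 1.52e-06). Oxidative stress genes had positive ones (17 of 21 positive and 0 negative, 19 and 0 adjusted over the list alone, camera adjusted p = 2.23e-09). The model called 4663 of 15058 genes, 2581 positive and 2082 negative, 1522 of them at least 2-fold. The calls of SNAI1, SNAI2 and ZEB1 were lost without A549 siCont A (adjusted p = 0.237 for SNAI1 and 0.0816 for ZEB1; 0.051 to 0.203 for SNAI2 over the 6 omissions that ended its call).

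The siKLF10 effect without TGFβ differed most for C5 (3.65 ± 0.179, adjusted p = 6.79e-16), which went from 2.86 ± 0.609 to 12.8 ± 1.39 CPM in Panc1 and from 309 ± 26.5 to 108 ± 12.1 CPM in A549. The 5 most negative differences, ADD2, NEFL, NLRP2, KCNK1 and VANGL2, were of genes with 50, 24, 88, 20 and 8 counts in Panc1 siCont and 0 or 1 in Panc1 siKLF10, and all 5 are among 431 genes of this model for which the siCont profile could account for at least 10% of the siCont level. Interferon-stimulated genes were more positive in Panc1 (12 of 28 positive and 0 negative, 15 and 1 adjusted over the list alone, camera adjusted p = 9.44e-07). Cholesterol genes were more negative (16 of 24 negative and 0 positive, 16 and 1 adjusted over the list alone, camera adjusted p = 9.81e-09). Of p53 targets 10 of 22 were more negative in Panc1 and 2 more positive (12 and 2 adjusted over the list alone, camera adjusted p = 0.00124). The largest was CDKN1A at −1.80 ± 0.121. VIM (−0.85 ± 0.111), ZEB1 (−0.45 ± 0.141) and FN1 (0.54 ± 0.148) differed, and SNAI1 (−0.60, adjusted p = 0.138), CDH1 (adjusted p = 0.944) and CDH2 (adjusted p = 0.548) did not pass. The model called 2597 genes, 1294 positive and 1303 negative, 550 of them at least 2-fold. This count was 1570 without A549 siKLF10 A and 1614 without A549 siCont B.

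Under TGFβ the siKLF10 effect differed between lines for cell cycle genes, with 22 of 30 more positive in Panc1 and 0 more negative (the same adjusted over the list alone, camera adjusted p = 1.45e-12). Examples were RRM2 (1.42 ± 0.102) and CCNE2 (1.27 ± 0.183). SNAI2 was more negative in Panc1 (−1.28 ± 0.215, adjusted p = 4.41e-05), as was ZEB1 (−0.53 ± 0.125). CDH1 (−0.73 ± 0.268, adjusted p = 0.0522), VIM (adjusted p = 0.147), FN1 (adjusted p = 0.098) and SNAI1 (adjusted p = 0.243) did not pass. The most positive difference was that of the glutamate transporter SLC1A1, at 0 and 6 counts in Panc1 and 326 and 511 counts in A549, and the most negative that of the neurotensin receptor NTSR1, at 141 ± 6.58 and 55.6 ± 7.22 CPM in Panc1 and 0 and 8 counts in A549. The model called 2979 genes, 1132 positive and 1847 negative, 553 of them at least 2-fold, and 1895 without A549 TGFβ A. The SLC1A1 call was lost in 7 of the fits that left a library out (adjusted p = 0.053 to 0.11), and the NTSR1 call without A549 TGFβ A (adjusted p = 0.0524) or A549 siKLF10 with TGFβ B (adjusted p = 0.222).

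The siKLF10 effects were compared across genes within and between lines. With and without TGFβ, which share no libraries, they correlated with r = 0.628 in Panc1 and 0.441 in A549, and 1510 genes rose and 1592 fell in both in Panc1, against 483 and 497 for independent lists. Between lines, r was 0.168 without TGFβ and 0.304 with it, and without TGFβ 311 genes rose and 506 fell in both lines, against 217 and 226 for independent lists. In all 4 siKLF10 comparisons 293 genes fell and 158 rose, of 12510 tested in both lines. The TGFβ and siKLF10 effects share the siCont libraries, and part of their overlap may come from those. Their r was 0.224 in Panc1 (0.111 across genes of at least 5 CPM), where 20 simulated draws with no effect averaged 0.483 (0.438 to 0.526), and the covariance was 0.0558 against 0.0168 simulated, a difference of 0.039. In A549 r was 0.317 against 0.417 simulated (0.359 to 0.463), and the covariance 0.183 against 0.0365, a difference of 0.146. Real effects add variance that the draws lack and that can lower r. An r below the simulated values therefore does not show less overlap than shared controls give. Both effects were positive for 409 genes and negative for 633 in Panc1, against 319 and 364 for independent lists, and for 603 and 694 in A549, against 327 and 330. They went opposite ways for 694 genes in Panc1, against 682 for independent lists, and for 502 in A549, against 658.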

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

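The tests of short sequences, of the second expression profile and of the deposited table, and the regrouping of libraries, were chosen or given their bounds after the results had been seen, while the interactions and line differences had been planned.

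Genes whose TGFβ response differed between siKLF10 and siCont, by a test of the difference, numbered 584 in Panc1, with ZEB1 at 0.37, and 916 in A549, with FN1 at 0.92. Between lines the TGFβ response differed for 4663 genes. The differences, Panc1 minus A549, were 0.89 for SNAI1, −1.01 for SNAI2, −0.44 for ZEB1, 1.005 for CDH1, −1.24 for CDH2, −0.68 for VIM and 0.64 for FN1. The siKLF10 effect differed for 2597 genes without TGFβ, with KLF10 at −0.68, ZEB1 at −0.45, VIM at −0.85 and FN1 at 0.54. With TGFβ it differed for 2979 genes, with KLF10 at −0.69, SNAI2 at −1.28 and ZEB1 at −0.53.

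In A549 without TGFβ, 2758 genes differed in the libraries labelled siKLF10 although KLF10 mRNA was not lower. Exchanged siCont and siKLF10 labels would give a negative correlation with Panc1 across genes, and r was 0.168, which argues against an exchange. Genes whose 3′ UTR held the sequence with the lowest t in Panc1, CCAATGA, were also lower in A549. Its t without TGFβ was −14.46 in Panc1 and −10 in A549. For the mean siKLF10 effect it was −14.61 in Panc1 and −10.74 in A549, where the lowest over shuffled effects was −4.83. An siRNA lowering transcripts that match its short seed could give this pattern. The siRNA sequence is not given in the sources used here, and both lines were seen together when this scan was first made. The 2 KLF10 transcripts searched hold CCAATGA, CCCAATG and ACCAATG, of which only ACCAATG lies in the 3′ UTR. An siRNA against KLF10 matches KLF10 transcripts, so these matches do not count against a seed effect. KLF10 being lower earlier or in protein stays open, since over genes with no site in a transcript r between lines was 0.107, against 0.326 with a site in a 3′ UTR.

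In the Panc1 siCont libraries, most of 14 genes of at least 200 CPM in the authors' deposited A549 TGFβ table and under 1 CPM in a Panc1 group were higher than in the other groups, 9 of them in every library and not PDE3A, with a median of 1.05, 0.396 and 0.451% of the table's level in A, B and C against 0.111 to 0.179% elsewhere. Of 132 genes of at least 20 CPM in the table and under 1 CPM in the other Panc1 groups, 96.21% had an excess in siCont. The share was 41.6% of 4894 genes under 1 CPM both in the table and in those groups. The sets were not matched for level below 1 CPM, so low counts may account for part of the gap. RNA or reads of another cell type may be the source of the excess. Lowering of these genes by TGFβ and by siKLF10 as the whole cause is argued against by siCont A, which stood at a median of 2.7 times the mean of B and C (0.884 to 3.76 over the 14 genes), and a partial contribution stays open. A549 RNA as that source is argued against by CPLX2, a gene chosen after its values were seen, which averaged 3340 CPM in A549 siCont and had 1 count in all over the 3 Panc1 siCont libraries. Its base mean was 0 in the authors' deposited A549 TGFβ table.

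The authors' deposited A549 TGFβ table held a signal outside the count data, with a base mean of 17399 for KRT5 where the counts gave 2.08. Another normalization or annotation of the same libraries could not give that value, nor the authors' deposited table's 10143 for MUC2 or 0 for FGB where the counts gave 2723. Of base means in the authors' deposited table, 1.063% lay within 1% of those from the counts, against 100% in 4 other tables and 0.0687% in the A549 siKLF10 table of another annotation. The rank correlation of its base means with those from the counts was 0.732, against 0.935 for that other table, which is consistent with values computed from other samples. Its log2 fold changes had r = 0.153 with those from the counts, across genes, against 0.846 to 0.952 for the other tables. No biological explanation was tested.

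For each Panc1 comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split called 3839, 4700, 5513 and 5943 genes for TGFβ, siKLF10, siKLF10 under TGFβ and TGFβ after siKLF10, and the highest other split 0. For the Panc1 interaction 1 of 60 splits gave as many as 584 genes, the real one, and the highest other gave 19. These splits mixed libraries of all conditions, so the TGFβ and siKLF10 effects widened the spread within the drawn groups. Few calls were therefore likely in any other split, and the splits cannot decide whether chance gave the interaction count.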

How the results depend on the processing

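The fits without genes the second profile could supply or with a 3′ UTR site, and the lists without Panc1 siCont A, were chosen after the data were seen; all other alternatives were planned. DESeq2 size factors moved no count of calls by over 1.5 times, nor did omitting the low-count filter or fitting only the groups compared. DESeq2's Wald test called 1676 genes in A549 siKLF10 against siCont, 2647 in A549 siKLF10 under TGFβ and 554 in the A549 interaction; the cause was not tested. Among named genes DESeq2 kept the side of the threshold for 316 of 320, and leaving a library out for 1992 of 2100, with 92 calls lost.

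Of 99 list calls by camera, 37 held with an estimated correlation, and fry gave 168; fry compares no list with other genes. With fry p53 targets in Panc1 TGFβ after siKLF10 (adjusted p = 0.00611) and the KLF family in A549 TGFβ after siKLF10 (adjusted p = 0.0011) were called in the direction opposite to camera's; the cause was not tested.

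Without 1 library, calls ran from 349 (without siKLF10+TGFβ B) to 1035 (without siKLF10+TGFβ A) in the Panc1 interaction, and were 388, 375 and 386 without TGFβ A, B and C and 360 without siKLF10 C. In A549 the lone sample left is assumed to vary like the other groups. A549 siKLF10 ran from 1326 (siCont B) to 1638 (siKLF10 B), with 1396 without siCont A and 1355 without siKLF10 A. A549 siKLF10 under TGFβ ran from 2237 (TGFβ A) to 5409 (siKLF10+TGFβ A), with 2439 without TGFβ B. The A549 interaction ran from 379 (siCont B) to 2685 (siKLF10+TGFβ A), with 455 without siCont A, 401 and 400 without TGFβ A and B, and 384 and 545 without siKLF10 A and B. Line differences ran from 1570 (A549 siKLF10 A) to 2512 for siKLF10, with 1614 without A549 siCont B, and from 1895 (A549 TGFβ A) to 3321 for siKLF10 under TGFβ. Fewer libraries give fewer residual degrees of freedom. Both interactions had their highest counts without siKLF10+TGFβ A. In Panc1 the chi-square per degree of freedom of that library was 9.11 against B and 12.5 against C. It was 2.06 for B against C, but also 9.42 for siCont A against C and 10.5 for siKLF10 A against B. The A549 siKLF10+TGFβ pair had 11.4, the other A549 pairs 2.22 to 2.97, and 1 pair cannot show which library departed. Whether this spread caused the rises was not tested.

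Across genes of at least 5 CPM, r was 0.871 and 0.933 for the TGFβ response with and without siKLF10 in Panc1 and A549, 0.763 and 0.545 for the siKLF10 effect with and without TGFβ (0.458 in A549 with DESeq2 fold changes), 0.111 for TGFβ against siKLF10 in Panc1, 0.244 and 0.36 between lines for siKLF10 without and with TGFβ, and 0.107 and −0.0651 for TGFβ in Panc1 against siKLF10 in A549 and the converse. Over all tested genes these were, in the same order, 0.81, 0.893, 0.628, 0.441, 0.224, 0.168, 0.304, 0.0685 and −0.0372, and leaving out 1 library gave 0.787 to 0.823, 0.863 to 0.884, 0.595 to 0.653, 0.376 to 0.421, 0.201 to 0.282, 0.132 to 0.175, 0.247 to 0.299, 0.0459 to 0.0855, and −0.0434 to −0.0215. For TGFβ against siKLF10 in A549 r was 0.317 (0.232 to 0.411), and for TGFβ between lines 0.464 (0.446 to 0.463). The cause was not tested.

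Same-letter libraries deviated together by r of −0.413 to 0.612 in Panc1 and −0.0175 to 0.233 in A549, where other-letter pairs mirror these by construction. A shared batch by letter stays open; in Panc1 3 of 18 same-letter and 13 of 36 other pairs were over 0.1. With the replicate block calls were 3776 for Panc1 TGFβ and 1026 for the A549 interaction, and no count moved by over 1.5 times. Among 320 named-gene values 2 calls were lost and 2 gained, and among 260 list values also 2 and 2.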

Other observations

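The common list of siKLF10 falls was examined for short sequences only after the values had been seen, and the genes named here were chosen then.

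Genes that fell in all 4 siKLF10 comparisons numbered 293, against 6.8 for independent lists, and 158 rose in all 4, against 6.89. The comparisons with and without TGFβ are not independent within a line (r = 0.628 in Panc1 and 0.441 in A549). The values for independent lists are therefore too low a reference for agreement between lines. The largest mean falls were of NDUFAF3, an assembly factor of mitochondrial complex I (mean log2 −2.30), the integrin subunit ITGB5 (−1.96), MREG (−1.75), RABL5 (−1.73) and OSTC, a subunit of the oligosaccharyltransferase (−1.65). NDUFAF3 fell by 2.39 and 2.50 in Panc1 without and with TGFβ and by 1.75 and 2.55 in the A549 libraries labelled siKLF10.

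The 3 sequences with the lowest t in the Panc1 siKLF10 effects, CCAATGA, CCCAATG and ACCAATG, were picked from those effects, so their presence among Panc1 falls tests nothing. In A549, seen together with Panc1 when the scan was first made, t of CCAATGA was −10.74 for the mean siKLF10 effect, and a direct effect of the siRNA on transcripts with these sequences is a candidate explanation for part of the falls. NDUFAF3, ITGB5, MREG and RABL5 hold such a sequence in the 3′ UTR. Among the 10 largest siKLF10 falls per comparison, 7 and 9 held a transcript site in Panc1 without and with TGFβ. In A549 these were 5 and 1, and 40.75% of genes tested in both lines held a transcript site. Of 283 searched genes that fell in all 4 comparisons, 50.88% held a 3′ UTR site, against 15.9% of other genes. For a transcript site the shares were 69.61% and 40.04%. Of genes that rose in all 4, 16.56% held a 3′ UTR site, against 16.75% of others. Falls in Panc1 helped to choose the first set, so its shares are not a separate test. Leaving out genes with such a 3′ UTR site removed 2060 genes in Panc1 and 2168 in A549. Of these, 935 had been called in Panc1 siKLF10 and 585 in A549 siKLF10, so most of the drop to 3696 and 2107 calls is their removal. Under TGFβ, 1026 and 731 called genes were removed, and 4451 and 3232 calls remained.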
